A study of Mus musculus with 17 samples.

How the data were processed

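RNA from 17 single cells of adult mouse back skin was measured in one table. The mice carried a tamoxifen-inducible Cre recombinase under Prrx1 control and a Tomato reporter, so that cells with Prrx1 activity at the time of tamoxifen turned red and stayed red. Per the labels, the skin was digested with elastase and then collagenase, Tomato-positive cells were sorted and picked singly under a fluorescence microscope, and libraries were made with a 3' end kit (SMART-Seq v4 3' DE) followed by Nextera XT. Per the submitters' processing notes, TopHat2, Cufflinks and the mouse build GRCm38 were used. Their versions and settings are not given in the sources used here.

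The deposited values are on a log scale, taken here as log2 of FPKM plus 1. The base and the added constant are not stated in the sources used here, and every FPKM threshold below rests on that reading. Back-transformed with base 2, cell 1 summed to 592955, and the other cells to nearly the same value. With base e the sum of cell 1 would be 12675767. The design fixed before the data were examined had assumed linear FPKM, so each FPKM threshold was converted: FPKM 1 is a deposited value of 1, FPKM 5 is 2.58 and FPKM 10 is 3.46. The sorted deposited log2 values were the same in all cells apart from the tied lowest block, differing by at most 0.0165 at values above 3, which is the form that quantile normalisation gives. As a result every cell has 4369 genes at FPKM 1 or more and 2970 at FPKM 10 or more, so that genes detected per cell, summed expression and the share in the highest genes carry no information about a cell. Read counts and depth per cell are unknown. The number of genes at the lowest value ranged from 871 to 1766 per cell and was used as the measure of library complexity that remained.

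The table holds 8446 rows, of which 8431 (99.8%) matched GENCODE M21 on GRCm38 by Ensembl identifier. Coordinates and exonic lengths (the union of annotated exons) come from that annotation. A symbol with several rows was represented by the row with the highest mean, and 5 identifiers stood in 2 rows each. Genes of the fixed lists that have no row are not analysed here. They include Dcn, Sparc, Tagln, Ly6a, Krt14, Ptprc, Pecam1, Runx2, Mki67 and the mitochondrially encoded genes. Below, a measured gene is one that has a row. Why the other genes have no row is not known, so their absence says nothing about expression.

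All 17 cells belong to 1 group, and no animal is named for any cell. The cells were therefore treated together as 1 sample, with no p-value, standard error or count of changed genes. Counts of cells carry exact Clopper-Pearson 95% intervals where given, which cover counting error over cells only. Means and SDs are over the 17 cells. Detection means FPKM 1 or more. The gene lists and the naming rule were fixed before the data were examined. The rule names Prrx1, the 20 genes with the highest mean after leaving out ribosomal protein genes, mitochondrial genes and gene models, the 4 members of each list detected in the most cells, the 10 genes with the largest SD among genes detected in 4 to 13 cells, and the markers of another cell type in cells with 3 or more of them. One list member that the rule names is not reported here. A few other list members are named for comparison and were chosen after their values were seen.

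List coherence was the mean pairwise Pearson correlation over cells among list members detected in at least 3 cells, for lists with at least 4 such members, and its percentile among 10000 random lists of the same size matched on mean value in 20 bins. The percentile describes these libraries. On simulated data with the same 8446 genes, of which 7551 were eligible, 20 of 20 lists with a shared factor and 5 of 200 lists without one lay in the upper 2.5% of random lists. Each gene's values had been shuffled over cells, each list had 10 genes, and the factor had the same SD as each gene. The simulation therefore does not show how often weaker coherence, or coherence in lists of another size, would be found. Cells were compared by Spearman correlation over the same 7551 genes. Sets of cells with similar low values were found by average-linkage clustering into 3 sets on genes under 2.5 in all 17 cells. They were defined from the data and are not groups of the study. Alternatives covered the detection threshold, the pseudocount, rescaling each cell to one sum, multiplication by gene length, the gene filter, the correlation measure and the omission of cells. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.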

Results

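The transcriptomes of 17 single Tomato-positive cells from the back skin of adult Prrx1-CreERT;Tomato mice were measured. The mice had received tamoxifen once a day for 3 days. All cells form 1 group, so the data give levels and spreads over cells and no comparison between conditions. Values are deposited log-scale values, read as log2 of FPKM plus 1, and the depth of each library is unknown.

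Prrx1 itself, a homeobox transcription factor of limb and dermal mesenchyme, was detected in 17 of 17 cells (exact 95% interval 80.5% to 100%). Its mean was 5.41 (SD 1.31, n = 17 cells), with the lowest value, 2.63, in cell 7 and the highest, 7.31, in cell 16. The gene (ENSMUSG00000026586) lies on chromosome 1 from 163245119 to 163313710 in GRCm38. At FPKM 10 or more it was found in 16 cells. Among the other transcription factors of the list that holds Prrx1, Klf4 (mean 8.03, SD 0.94) and Ebf1 (mean 6.60, SD 1.41) were detected in all 17 cells and Zeb2 (mean 5.43, SD 2.33) in 16. Twist1 was detected in 14 cells, Twist2 in 11, and the paralog Prrx2 in 9 with a median of 1.10. All 14 members of this list were in the table and none was missing from every cell. Because Prrx1 was detected in each cell, joint detection with it equals a gene's own count of cells. Of 23 other stem and transcription factor genes, 7 were detected together with Prrx1 in all 17 cells, among them Pdgfra, Itgb1, Itgav, Vcam1 and Cd44.

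The cells carried dermal fibroblast transcripts throughout. Of the 20 fibroblast markers 18 were measured, and each cell had 17 or 18 of them. Col3a1 (mean 11.15, SD 1.31) and Col1a2 (mean 10.98, SD 1.19), which encode the fibrillar collagens of dermis, were the highest, followed by Serpinf1 (mean 10.36, SD 0.99) and Mfap5 (mean 9.87, SD 1.35). The platelet-derived growth factor receptor Pdgfra was detected in 17 cells, whereas Thy1 was detected in 15 and Pdgfrb in 10. At FPKM 10 or more the cells still had 14 to 18 of the markers. The sex-linked list was led by the Y-linked genes Ddx3y and Eif2s3y, each detected in 14 cells, then Uty in 4, while Kdm5d was detected in none. Each cell had at least 1 of these genes, but at FPKM 10 or more cells 10, 16 and 17 had none. Xist had no row, so the list could not show female cells.

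**Figure D1:**
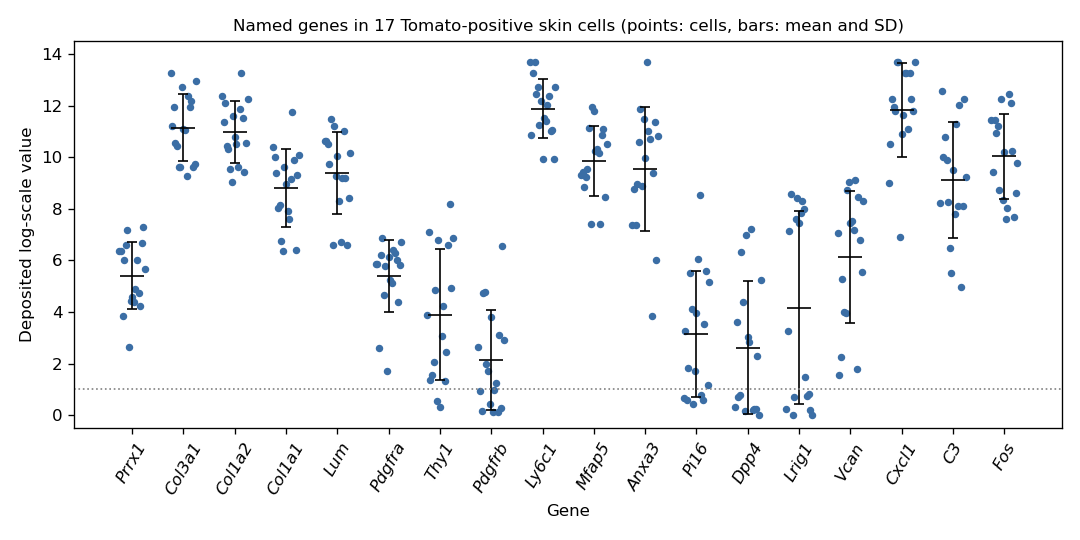
Deposited log-scale values of 18 genes in the 17 cells. Each point is 1 cell, the black bars give the mean and SD over cells, and the dotted line marks a value of 1; Prrx1 lies above that line in all 17 cells and Pdgfrb in 10.

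Matrix genes were broadly expressed. Of 17 measured collagen genes, 13 were detected in all 17 cells. Besides Col3a1, Col1a2 and Col1a1 (mean 8.82, SD 1.50), the fourth by rank was Col5a2 (mean 7.73, SD 0.95). Among 19 measured proteoglycans and glycoproteins, 11 were detected in all cells, led by Lum (mean 9.40, SD 1.60), Fn1 (mean 8.52, SD 1.10), Bgn (mean 7.96, SD 1.68) and Fbln2 (mean 7.77, SD 0.90). All 23 matrix remodelling genes were measured and 17 of them were detected in every cell, with Pcolce, an enhancer of procollagen processing, at a mean of 10.90 (SD 1.17), the cathepsin gene Ctsl at 8.83 (SD 0.97), the protease inhibitor gene Timp2 at 8.53 (SD 0.95) and the collagen chaperone gene Serpinh1 at 8.26 (SD 0.92).

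Of the lists that describe positions within skin, the fascia and adventitia list was the most fully detected. Of its 12 measured members, 7 were detected in all 17 cells and each cell had 9 to 12. Ly6c1 had a mean of 11.89 (SD 1.16), Mfap5 of 9.87, Anxa3 of 9.54 (SD 2.40) and Gfpt2 of 6.96 (SD 2.53). Pi16 and Dpp4, surface markers of adventitial and fascial fibroblasts, were detected in 12 and 9 cells, and cell 11 held the highest value of both, 8.54 and 7.24. The papillary list had 5 measured members, of which Ntn1 was detected in 13 cells, Lrig1 in 10, Col18a1 in 7 and Dkk2 in 3. Among 8 measured reticular genes Gpx3 (mean 11.57, SD 1.62) and Mgp (mean 6.66, SD 2.05) were detected in all cells, Tgm2 in 10 and Cd36 in 9. Cd36 was low throughout, at most 3.02, and under FPKM 10 in every cell. Of 6 measured dermal papilla genes Vcan was detected in 17 cells, Fgf7 in 14, Alpl in 4 and Bmp4 in 3. Of 4 dermal sheath genes Abi3bp was detected in 17 cells, Mef2c in 9, and Acta2 and Myl9 in 6 each. Acta2 and Myl9 lay between 1.10 and 2.00 in cells 1 to 5, and were otherwise detected in cell 8 and cell 14 respectively. Among 7 measured Hox genes Hoxc6 was detected in 10 cells, Hoxc8 and Hoxb2 in 5 each and Hoxc4 in 3. The lists differ in how many members were measured and share some, so their counts do not rank the positions.

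Stem cell and lineage genes were unevenly detected. The median per cell was 8 of 10 stem cell genes and 6 of 11 adipogenic genes, the latter near the share over all rows. Of 10 measured mesenchymal stem cell genes, Itgav (mean 6.47, SD 2.53), Itgb1 (mean 5.98, SD 1.02), Vcam1 (mean 5.48, SD 1.79) and Pdgfra (mean 5.39, SD 1.39) were detected in all cells. Of 11 measured adipogenic genes, Cebpd (mean 5.21, SD 1.97) and Lpl (mean 5.09, SD 2.26) were detected in 17 cells and Plin2 and Cebpb in 16, whereas Pparg, the master regulator of fat cell formation, was detected in 2. Only 2 of 13 osteogenic genes were measured, Col1a1 in 17 cells and Alpl in 4. Only 3 of 13 chondrogenic genes were measured, with Prg4 in 17 cells and Sox5 and Sox9 in 9 each. At FPKM 10 or more none of these 3 was found in as many as 9 cells.

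Chemokine, complement and immediate-early genes were widely detected. The neutrophil chemokine Cxcl1 (mean 11.83, SD 1.81) and the monocyte chemokines Ccl7 (mean 10.24, SD 2.60) and Ccl2 (mean 9.90, SD 3.01) were detected in all 17 cells, as was Ccl11 (mean 7.07). All 10 complement genes were measured and 6 were detected in every cell, with Serping1 at a mean of 9.95 (SD 1.63), C3 at 9.12 (SD 2.26), C4b at 7.94 (SD 3.05) and C1s1 at 6.67 (SD 1.45). Of 19 immediate-early and heat-shock genes, which tissue digestion is known to induce, 13 were detected in all cells, led by Fos (mean 10.03, SD 1.65), Hspa8 (mean 9.01, SD 0.90), Zfp36 (mean 8.71, SD 1.25) and Hsp90aa1 (mean 8.47, SD 1.83). There were no undigested cells to compare with.

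Signalling genes were detected to differing degrees. Of 18 measured BMP and TGF-beta genes, Id3 (mean 8.66, SD 1.84), Tgfbr2 (mean 6.41, SD 1.51), Bmp1 (mean 5.57, SD 1.50) and Tgfbr3 (mean 5.27, SD 1.91) were detected in all cells. Of 17 measured IGF, FGF and PDGF genes, Igfbp6 (mean 10.26, SD 0.78), Igfbp7 (mean 7.58, SD 2.37), Igf1 (mean 6.97, SD 3.22) and Fgfr1 (mean 5.71, SD 1.73) were. Of 12 measured Wnt genes only Sfrp4 was detected in all cells, followed by Ctnnb1 in 14, Tcf7l2 in 13 and Sfrp1 in 11. The median per cell was 7 of these 12, near the share over all rows. The nuclear receptor genes Nr3c1 and Thra were each detected in 14 cells and Esr1 in 12. Of 9 measured quiescence and cell cycle inhibitor genes, Cdkn1a (mean 7.24, SD 2.38) and Gas6 (mean 6.15, SD 2.56) were detected in all cells, Gas1 in 10 and Rb1 in 8. Of 5 measured cell cycle genes Pcna was detected in 15 cells, and Birc5, Ube2c and Cdk1 in 4 each.

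The 20 genes with the highest means were S100a10 (12.57), Plac9b (12.19), S100a11 (12.05), Ly6c1, Mt2 (11.83), Lgals1 (11.83), Cxcl1, Plac9a (11.80), Gpx3, Ifitm3 (11.40), Ubb (11.32), S100a4 (11.32), B2m (11.31), Ecm1 (11.16), Col3a1, Ftl1 (11.14), Col1a2, Pcolce, Tpt1 (10.82) and Actb (10.80). Plac9a and Plac9b are near-identical copies and their reads may be split between them. Of these 20 genes 9 stayed among the 20 highest when values were multiplied by gene length. B2m, Tpt1 and Actb also led the housekeeping list together with Eef1a1 (mean 10.26, SD 0.72). The 10 most variable genes among those detected in 4 to 13 cells were Rpph1 (SD 4.32), Rny1 (SD 3.90), Brd2 (SD 3.78), Rab26os (SD 3.77), Lrig1 (SD 3.73), Smim4 (SD 3.72), Cxcl10 (SD 3.67), Srsf2 (SD 3.66), Cfd (SD 3.64) and Magohb (SD 3.64). With a pseudocount of 0.1 only 4 of these 10 stayed among the 10 most variable.

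Markers of other cell types were sparse. Of 9 other cell types, 3 had the 3 measured markers that the rule needs, so the rule could find no cell of the remaining 6. By that rule 9 cells had 3 or more markers of another type. Cells 1 to 5 had pericyte or smooth muscle genes, with Acta2, Myl9 and Rgs5 between 1.04 and 2.00 in each, Higd1b between 1.11 and 2.25 in cells 1 to 3, Kcnj8 at 4.98 in cell 4 and 6.48 in cell 5, and Abcc9 at 2.82 in cell 4. No cell outside cells 1 to 5 met the rule for this list, and no cell did at FPKM 5. Single genes of the list were highest elsewhere, with Acta2 at 5.64 in cell 8, Myl9 at 4.01 in cell 14 and Higd1b at 4.32 in cell 16. Kcnj8 and Abcc9 were highest within cells 1 to 5. Cells 1 to 5 form 1 of the sets with similar low values described below, and nothing here separates a cell type from what those libraries share. The list was at the 91.51 percentile of random lists (99.99 by Spearman) and at 59.74 with set means subtracted. Cells 8 and 12 had the endothelial genes Ly6c1, Tek and Plvap, and cell 17 had Ly6c1, Tek and Esam, although Ly6c1 was high in all cells and also stands in the fascia list. Cells 16 and 17 had the adipocyte genes Fabp4, Cfd and Car3. At FPKM 10 or more only cell 16 met the rule, with Fabp4 at 6.52, Cfd at 9.70 and Car3 at 5.85. Among lists with too few measured markers, Krt10 was detected in 5 cells and Krt79 in 1, Csf1r in 5, Mbp in 12, S100b in 5, Mitf in 5 and Alas2 in 14. At FPKM 10 or more, Alas2 was found only in cells 2, 11 and 16 and Mbp only in cells 10 and 16. The skeletal muscle and mitochondrial lists had no measured member.

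Several lists varied together from cell to cell. Of 25 lists tested, 9 lay in the upper 2.5% of matched random lists, where 0.625 lists would lie by that limit alone. Some lists share members, so these are not 9 separate results. The fibroblast markers include Col1a1, Col1a2, Col3a1 and further genes of the collagen list. Mfap5 is a fibroblast marker and a fascia gene, and Cd55 is in both the complement and the fascia list. The 17 collagen genes had a mean pairwise correlation of 0.363 (Spearman 0.341), the 10 complement genes 0.356 (Spearman 0.378), the 19 immediate-early genes 0.285 (Spearman 0.242) and the 12 fascia and adventitia genes 0.216 (Spearman 0.246), each at the 100th percentile after rounding. The other lists were the fibroblast markers (0.166), 4 cell cycle genes (0.456) and BMP and TGF-beta genes (0.108). They also included quiescence and cell cycle inhibitor genes (0.130) and adipogenic genes (0.165). Only cells 11, 15, 16 and 17 had 3 or more cell cycle genes, and at FPKM 10 no cell had more than 2. Cells 15 to 17 form 1 of the sets with similar low values described below. With set means subtracted the cell cycle list was at the 99.81 percentile. The cell cycle list could not be tested in cells 6 to 14 alone. Leaving out cell 8 took the adipogenic list to the 96.06th percentile and the quiescence and cell cycle inhibitor genes to the 97.17th. The adipogenic list was also at the 85.62 percentile with no filter beyond detection in 1 cell, and at 90.91 with the means of the 3 sets of consecutively numbered cells (1 to 5, 6 to 14 and 15 to 17) subtracted, where 8 of the 9 lists kept their place. Collagen genes were lowest on average in cell 15 (4.37) and highest in cell 8 (7.84), whereas complement genes were lowest in cell 14 (3.22) and highest in cell 3 (8.40). The stem cell genes (0.001, percentile 52.88) and proteoglycans (0.012, percentile 63.93) did not stand apart from random lists.

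**Figure D2:**
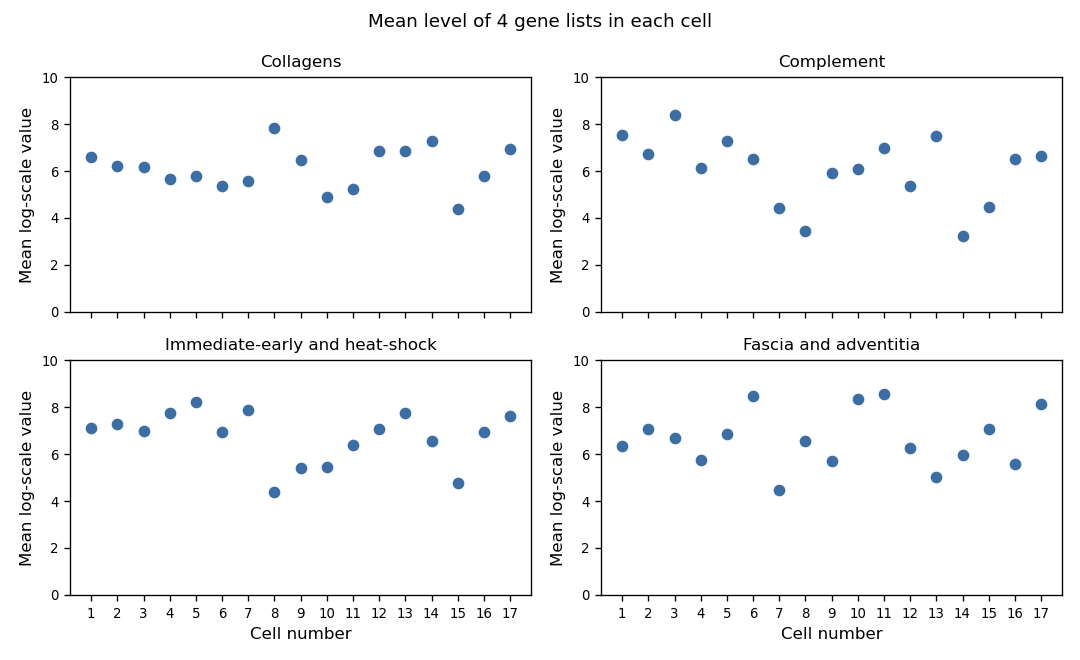
Mean deposited log-scale value of the members of 4 gene lists in each of the 17 cells. Each point is 1 cell; collagen means run from 4.37 in cell 15 to 7.84 in cell 8 and complement means from 3.22 in cell 14 to 8.40 in cell 3.

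The cells resembled each other to a similar degree. The median Spearman correlation between pairs was 0.464, and a cell's median to the other cells ranged from 0.416 in cell 16 to 0.493 in cell 6. Low values were more alike within sets of consecutively numbered cells. Clustering on 224 genes under 2.5 in all cells separated cells 1 to 5, 6 to 14 and 15 to 17, with a mean pair correlation of 0.276 within and 0.0977 across these sets. The sets were formed from these same correlations, so a gap between the 2 values was built in. With sets formed from a part of these genes, the gap in the remaining 112 genes was 0.153.

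**Figure D3:**
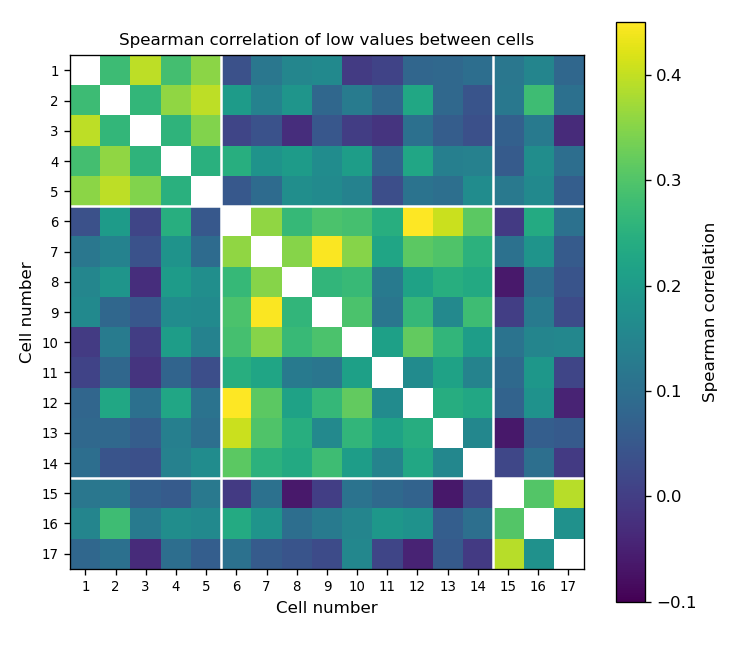
Spearman correlation between each pair of cells over 224 genes under 2.5 in all 17 cells, with both axes giving the cell number. White lines separate cells 1 to 5, 6 to 14 and 15 to 17, within which the mean correlation is 0.276 against 0.0977 across them. These sets were formed from the same correlations.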

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

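The covariate regression on genes above the lowest value, the settings that subtract means of the 3 sets of cells or use cells 6 to 14 or pairs within sets only, and the one with cells 1 to 5 left out were chosen after the data were seen. Leaving out cells with under 1000 genes removed none, and another pseudocount or rescaling cannot move a rank correlation between cells, so these settings show nothing about stability. The median number of genes detected per cell was 7236 above the lowest value, where cells differ (6680 to 7575), 3417 at FPKM 5, 2970 at FPKM 10, 4707 after rescaling and 4900 after multiplication by length. The number at FPKM 10 is the same in every cell, as is that at FPKM 1, through the normalisation. Fibroblast markers per cell were 18 above the lowest value, after rescaling and after multiplication by length. Cells with 3 or more markers of another type numbered 17 above the lowest value, 3 at FPKM 5, 1 at FPKM 10 (also 1 with cells 1 to 5 left out) and 1 with a minimum of 5 markers. Genes found with Prrx1 in all cells numbered 17 above the lowest value and 0 at FPKM 10, where Prrx1 itself misses cell 7. Median cell similarity was 0.491 with no filter beyond 1 cell, 0.515 by Pearson and 0.495 for pairs within sets. Of the 10 most variable genes 4 stayed with a pseudocount of 0.1 and 3 with no filter beyond 1 cell. The share in the 50 highest genes, 27.9%, was 29.8% without ribosomal protein genes, 38.8% for 100 genes and 24.4% after multiplication by length. The count of coherent lists, 9 of 25 tested, was 12 with a pseudocount of 0.1. In cells 6 to 14 it was 6 of the 18 lists that could be tested. There the quiescence and cell cycle inhibitor genes were at the 85.42 percentile and the adipogenic list at 85.60. Prrx1 was detected in 16 or 17 cells. Position genes, without the Hox list, detected in at least 9 cells numbered 22, from 15 at FPKM 10 to 33 above the lowest value. Stem cell and lineage genes numbered 18, from 13 to 25. For single position, stem cell and lineage lists the median number of members per cell moved by at least its SD over cells in 19 cases. All were with another threshold except 1 with multiplication by length. The causes were not tested beyond what the settings themselves fix, and with depth unknown no detection limit can be given.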

Other observations

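The tests of gene level opposition between lists were chosen after the data were seen. The tests of gene length, shared low values and collagen coherence were set before their results were seen, but the set of ribosomal protein genes was corrected and the comparison for animals or skin sites was recast after their first results were seen.

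Among single cells, cell 16 held the highest Prrx1, Twist1, Zeb2 and Tcf4 values together with the highest Cfd, 9.70, a complement factor made in fat. It also stood apart as a library, with the highest share in ribosomal protein genes (14.8% against a median of 9.27%), the lowest median similarity to other cells (0.416) and the highest Rpph1, Brd2, Rab26os and Srsf2 values. Cell 11 held the highest Pi16, Dpp4, Procr (10.58), Cd55 (9.66) and Sema3c (8.57) values, all members of the fascia and adventitia list, with a fascia mean of 8.56 against 8.45 in cell 6, which ranks first (0.822 against 0.815) when each gene is centred and scaled to unit SD. These are single cells with no replicate.

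Collagen genes varied together from cell to cell. Subtracting the mean of each set of consecutively numbered cells left a mean correlation of 0.382. Regression on the number of genes above the lowest value left 0.380, and both were at the 100th percentile. This argues against differences between these sets, or a linear effect of that number, as the whole cause. Depth and processing differences between cells of a set could not be tested. Among random lists matched on mean and exonic length the percentile was again 100, which argues against gene length. No biological explanation was tested, and differences in RNA content hidden by the normalisation stay open.

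The highest values belonged to short genes: the median exonic length was 1656 bases for the 100 highest genes and 4414 for all genes. A candidate explanation is division by gene length of reads that come from 3' ends. Over 76 canonical ribosomal protein genes the slope of the mean value on length was -0.381 per doubling (bootstrap 95% interval -0.707 to -0.0707), and with paralogs and retrocopies it was -0.403 over 88 genes. The interval leaves out 0 but holds the bound of -0.5 set in advance, so the explanation stays open. A first choice of genes by name prefix, which took in genes that are not ribosomal proteins, had met the bound. It was corrected after that result was seen.

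Low values were shared within cells 1 to 5, 6 to 14 and 15 to 17. The same sets came from one part of the low genes, in the remaining 112 genes the pair correlation was higher within sets by 0.153, and differences in library complexity left most of the gap, 0.164 of 0.178. These values rest on Spearman correlations without centring. A different animal or skin site for each set cannot be told apart from joint processing. With each gene centred and Pearson correlation used, genes at FPKM 10 or more in all cells had a gap of 0.0283 against 0.0533 for low values. The planned comparison, by Spearman correlation without centring, gave 0.0415 against 0.178. That result lay on the side set in advance against a different animal or site. It was set aside because differences in level between genes dominate those correlations, and the correlation measure changed along with the centring. In both comparisons the sets had been formed on the low values, which favours a larger gap there. Reads passed between cells processed together stay possible: over 245 genes high in 1 cell only, other cells of its set had a mean low value of 0.324 against 0.227 in the other sets (recipient differences not removed), which shared animals or sites could also give, and the symmetry between donor and recipient cells, 0.224, lay between the bounds set.

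Fascia and adventitia genes ran slightly opposite to collagens, with a mean correlation between lists of -0.0845, and -0.0882 with set means subtracted. It stayed negative with each cell left out, at most -0.0554 without cell 11, and whether this reflects a pair of opposed fibroblast programmes or a few libraries was not decided. Of 21 pairs of lists, 18 lay outside the middle range of random pairs, and collagens lay below it with 5 of 6 lists, so the random pairs do not single out this pair. Fascia and adventitia genes were more opposed to the immediate-early genes (-0.111, and -0.108 with set means subtracted), with which complement genes (0.177) and cell cycle inhibitors (0.148) rose. A response to digestion shared by several lists was not tested.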
